A study of Homo sapiens with 12 samples.

How the data were processed

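RNA was measured by sequencing of polyadenylated transcripts in 12 libraries: decidual cells and chorion trophoblast cells, each with vehicle or LPS at 100 ng/mL, 3 libraries per group. Per the labels' protocols, RNA was isolated with a column kit and libraries were made with the NEBNext Ultra Express kit. The deposited values are raw read counts per Ensembl gene, 1 column per library, made by the authors; reads were trimmed with Trimmomatic and aligned with STAR 2.7.11a to hg38, per the submitters' processing notes. The program that counted reads, its annotation release and its strand setting are not given in the sources used here, so overlapping and antisense genes are treated as uncertain, as are genes with near-identical copies.

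The table held 61544 gene rows, of which 61445 matched a symbol, 87 more were named from GENCODE 29, and all columns matched 1 library. Left out were 566 rows of Y-linked genes, X-inactivation transcripts and pseudoautosomal copies, which could describe a donor, leaving 60978 rows, 57779 of them with a GENCODE 29 position on GRCh38. Totals ran from 41384385 to 67759762 counts per library, so a gene at 1 CPM rests on 41.4 to 67.8 counts, and the 10 most abundant genes took 5.85% to 8.41% of a library. Repeats were looked for in 8 within-group pairs, leaving out the 2 libraries with the other type's profile. None of the 8 agreed within sampling noise (mean chi-square per gene with at least 50 counts 2.29 to 15.1), so none was counted as a repeat.

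Groups came from the labels alone. The comparisons, fixed before the data were examined, were LPS against vehicle in DEC, the same in CTC, the difference of these effects, and CTC against DEC with vehicle. One edgeR fit over all 12 libraries (edgeR 4.0.16, limma 3.58.1, R 4.3.3) used TMM normalization, filterByExpr (minimum count 10) and the quasi-likelihood test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The ± of a log2 fold change is its size divided by the square root of F, which understates the error where a group has few counts. It was below the counting error for 16 of 43 results that the naming rule took over the 12 libraries and 133 of 471 over the 9, and is not printed there. Of these 471, 177 were run in the alternatives. Replicate numbers carry no stated meaning, so no block was used. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and members were also adjusted over the list alone. The 25 lists covered TLR4 signalling, NF-kB, cytokines, chemokines, type I interferon response, antigen presentation, complement, prostaglandin synthesis and labour, matrix proteases, structural matrix, NRF2, unfolded protein and stress response, glycolysis and hypoxia, inflammasome and cell death, cell cycle, tolerance and checkpoints, decidualization, and markers of trophoblast, syncytiotrophoblast, stroma, smooth muscle, macrophages, NK and T cells, endothelium and endometrial glands. Some members stand in more than 1 list.

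Cell identity was checked after the data were seen. Genes with at least 20 CPM in one cell type and under 0.5% of that in the other gave 190 trophoblast-specific and 143 decidual-specific genes, and a library was set aside in the added fits where the other type's genes exceeded 1% of their usual level. A low share in most libraries follows in part from this choice, which used all 12, while the marker lists of the scores below were fixed beforehand. The limit was passed in 3 libraries, 2 of which were nearer the other cell type. Mean log2 marker scores (trophoblast minus stromal, prior count 1) ran from -6.65 to -6.18 in the remaining DEC libraries and from 5.99 to 6.36 in the remaining CTC libraries, against 6.19 and -6.72 in these 2 and -4.34 in the third. Labels were never reassigned. Fits over the 10 libraries without these 2, and over the 9 without all 3, were added for every comparison. In the 9, both DEC groups and the CTC LPS group hold 2 libraries each, and the spread is pooled over the groups.

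Genes named in the text were taken by a rule fixed beforehand: an adjusted p under 0.05, CPM ranges of the groups that do not overlap (which chance gives in 10% of genes for 3 against 3 libraries, 20% for 3 against 2 and 33.3% for 2 against 2), a mean of at least 1 CPM in a group, and a plain symbol outside the sex chromosomes and known copy polymorphisms; then the 14 largest rises and 8 largest falls with LPS, the 8 at each end for the other comparisons, up to 4 members of each list with the smallest p, and TLR4, LY96, CD14 and MYD88. The same rule was applied to the 9-library fit, which departs from the plan in that this fit was chosen after the data were seen.

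Alternatives were DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, no low-count filter, the 2 groups compared fitted alone, a replicate block, each library left out in turn, and an estimated correlation for the lists; the added fits repeat them. Size factors in the 9 libraries moved the median of all genes by less than 0.1 on the log2 scale and the shares of higher calls by less than 1 percentage point. Over the 12 they moved the balance more: higher and lower calls went from 35 and 8 to 36 and 13 in DEC, from 1 and 7 to 0 and 9 in the difference, and from 5613 and 6130 to 5969 and 5871 in vehicle. The scripts' statistics were tested on simulated counts with 200 genes changed by known folds. The simulated counts took the spread of each fit, but no simulated library carried the other cell type's profile. The shares for the 12 libraries therefore need not hold for the real ones. Over 12 libraries as labelled (19865 genes) the test recovered 14% of 4-fold and 0% of 2-fold changes in DEC and 38% and 2% in CTC; over the 9 (20643 genes) it recovered 74% of 1.25-fold and 98% of 2-fold changes in DEC and 70% and 100% in CTC. False calls were 22.22% and 4.76% of the calls in DEC and CTC over the 12, and 6.53% and 3.74% over the 9.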

Results

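Polyadenylated RNA was sequenced from cultures of 2 cell types of the human fetal membranes, each given ultrapure lipopolysaccharide (LPS, the endotoxin of Gram-negative bacteria) at 100 ng/mL or PBS as vehicle. Decidual cells (DEC) are maternal stromal cells of the uterine lining, here primary cultures, and chorion trophoblast cells (CTC) are the fetal epithelial cells that lie against them. Each of the 4 groups held 3 libraries, 12 in all. The length of exposure is not given in the sources used here. The media and the origin of the cell types differed, so cell type, origin and medium could not be separated. Total gene counts ran from 41384385 to 67759762 per library, 27814 to 34153 genes had at least 1 count, and mitochondrial transcripts took 3.13% to 5.49% of the counts. No label says that libraries of a group came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical. Values are CPM (counts scaled to the library total) as mean ± SD. Log2 fold changes also use TMM factors, so between cell types they differ from the ratio of the CPM. Their ± is an error read from the test's F statistic, left out where it was below the counting error.

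The markers of both cell types were read first, because every comparison rests on them. In 9 libraries, genes specific to the other cell type stood at a median of 0.0805% to 0.147% of their level in that type, over 190 trophoblast-specific and 143 decidual-specific genes. In 1 library of each LPS group the profile was that of the other cell type. The library labelled DEC LPS held trophoblast-specific genes at 100.4% of their trophoblast level and decidual genes at 0.11%, and the library labelled CTC LPS held decidual-specific genes at 98.8% and trophoblast genes at 0.0782%. A vehicle library labelled DEC held trophoblast-specific genes at 1.55%. All 12 libraries were analysed as labelled. Each comparison is also given for the 9 libraries left without these 3 (2 DEC vehicle, 2 DEC LPS, 3 CTC vehicle and 2 CTC LPS libraries), a choice made after seeing the data. The biological coefficient of variation was 0.608 over the 12 libraries and 0.0295 over the 9.

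**Figure D1:**
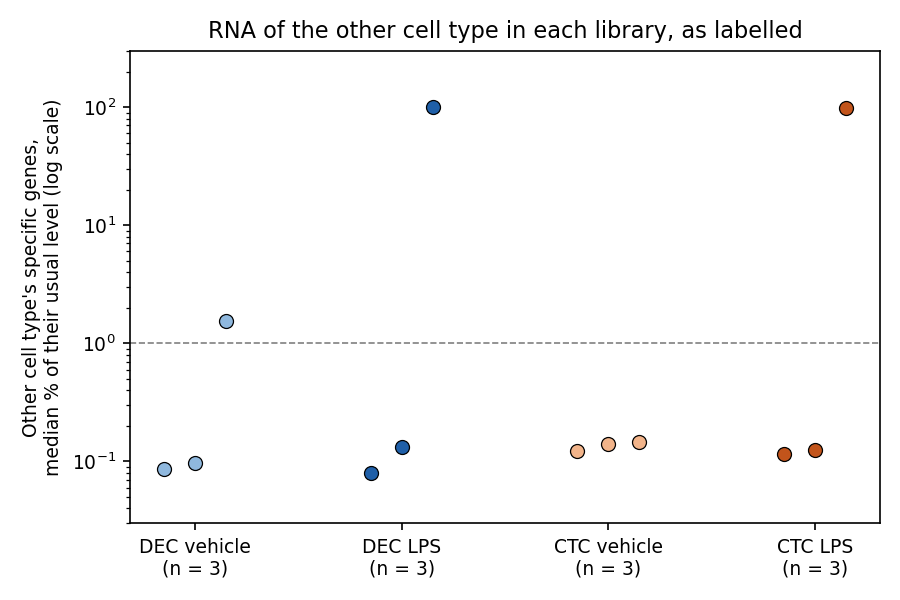
RNA of the other cell type in each of the 12 libraries, as the median percent of the usual level of that type's specific genes (vertical log axis), by labelled group; each point is 1 library and the dashed line marks 1%. One library of each LPS group lies near 100% and 1 DEC vehicle library at 1.55%, while the other 9 lie between 0.0805% and 0.147%.

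The first comparison asked which transcripts LPS changed in decidual cells. LPS raised the interferon-induced gene IFI6, the NF-kB inhibitor TNFAIP3, the complement component C3 and the aldose reductase AKR1B1, which also makes prostaglandin F. IFI6 went from 9.07 ± 1.17 CPM with vehicle to 212.8 ± 12.9 CPM with LPS (n = 3 each, log2 fold change 4.46 ± 0.25). TNFAIP3 went from 6.5 ± 0.514 to 40.7 ± 1.22 CPM (2.54 ± 0.16), C3 from 1.87 ± 0.326 to 94.9 ± 49 CPM (5.64 ± 0.81) and AKR1B1 from 290.9 ± 7.67 to 1140.5 ± 82.7 CPM (1.88 ± 0.24). Over the 12 libraries as labelled, 43 of 20682 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 35 higher and 8 lower with LPS, 27 of them by at least 2-fold. The count and its balance were not stable: DESeq2 gave 281 (146 higher and 135 lower), the 2 groups fitted alone 2, no low-count filter 23 and a replicate block 1. With each library left out in turn it was 15 to 67. The other risers that the naming rule took were the antiviral genes RSAD2 (4.70), CMPK2 (3.28) and IFIH1 (1.91), the prostaglandin synthase PTGS2 (3.16), GNA15 (4.50), LCP1 (3.55), C15orf48 (3.14), LRRC15 (3.11) and KYNU (2.22). The epithelial transcription factor EHF had 2 counts over the vehicle libraries (0.0161 CPM) against 1.04 CPM with LPS. The fallers were SLC14A1 (-2.43), COPG2IT1 (-1.57, uncertain because it overlaps another gene), AKAP6 (-1.14), MBOAT1 (-1.12), MEST (-0.87) and STON1 (-0.77). With the trophoblast profile in 1 of the 3 DEC LPS libraries, this fit favours genes whose level in DEC with LPS matches that in CTC. IFI6 was at 208.6 ± 6.95 CPM and TNFAIP3 at 40.6 ± 0.699 CPM in CTC with vehicle (n = 3). Other risers varied widely between the DEC LPS libraries and stood higher in CTC with vehicle. They were LCP1 (195.3 ± 157.7 CPM in DEC with LPS, 360.7 ± 9.47 CPM in CTC with vehicle), PTGS2 (3.58 ± 2.35 and 5.95 ± 0.631 CPM) and KYNU (4.04 ± 1.97 and 5.41 ± 0.284 CPM). Their log2 fold changes as labelled take in the library with the trophoblast profile.

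Of the 25 gene lists, 9 passed over the 12 libraries in camera with a preset correlation of 0.01. The NF-kB list (3 of 23 members past the threshold, 4 when adjusted over the list alone), the cytokines (0 of 21, 5 alone), the chemokines (0 of 16, 6 alone) and the type I interferon response (4 of 43, 8 alone) ranked higher with LPS. Glycolysis and hypoxia (0 of 23, 0 alone), cell cycle (0 of 27, 0 alone) and trophoblast markers (0 of 23, 0 higher and 1 lower alone) did too. Stromal markers (0 of 22, 0 alone) and smooth muscle markers (0 of 12, 0 alone) ranked lower. None of the 25 passed with an estimated correlation, where the smallest adjusted p was 0.531. The stromal markers had a median log2 difference of -0.47 and the smooth muscle markers of -0.70 in this contrast, in which 1 of the 3 DEC LPS libraries held trophoblast-specific genes at 100.4% of their trophoblast level.

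LPS changed more genes of decidual cells in the 9 libraries. CXCL8, the main neutrophil attractant, went from 3.79 ± 0.102 CPM to 495.8 ± 21.3 CPM (n = 2 each, log2 fold change 7.05, adjusted p = 1.94e-47), and CXCL1, which acts on the same receptor CXCR2, from 0.248 ± 0.00834 to 113.5 ± 0.864 CPM (8.85, adjusted p = 4.03e-42). The mitochondrial superoxide dismutase SOD2 reached 1899.4 ± 6.16 CPM from 186.2 ± 0.774 CPM, and the antiviral GTPase MX1 reached 223.0 ± 0.975 CPM from 7.17 ± 0.0121 CPM. In all, 3710 of 20988 genes passed, 1774 higher and 1936 lower, and 414 of them by at least 2-fold. Which side was larger changed with 1 DEC library left out (1470 higher and 1388 lower, or 1268 and 1572). All 43 genes called over the 12 libraries were among them with the same sign. With only the 2 libraries of the other type's profile left out, 2797 genes passed (1371 higher and 1426 lower), and 2634 of these were shared, all with the same sign.

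Of the 43 measured interferon genes in the 9 libraries, 41 rose and none fell (median log2 fold change 1.77, 41 when adjusted over the list alone). OAS1 rose by 8.05, IFI44L by 6.11, OAS2 by 5.54, MX2 by 5.43 and IFI27 by 5.12. Of the 16 chemokines, 11 rose and none fell (11 rose and 1 fell when adjusted over the list alone). Besides CXCL1 and CXCL8 these included CXCL6 (7.62), CXCL2 (6.46), CXCL3 (5.65) and CXCL5 (5.18). The monocyte attractant CCL2 went from 54.3 ± 1.1 to 191.2 ± 9.93 CPM. The NF-kB list had 19 of 23 members higher and none lower (22 alone), among them TNFAIP3 (2.75), the RNase ZC3H12A (2.44) and the adhesion molecule ICAM1 (2.36). Of 21 cytokines, 15 rose and 1 fell (16 and 1 alone), with the granulocyte growth factor CSF3 at 6.87, IL6 at 4.32, LIF at 2.05 ± 0.08 and IL32 at 1.91 ± 0.06. Of 19 members of the antigen presentation list 18 rose (18 alone), by less: the proteasome activator PSME2 by 0.90, the proteasome subunit PSMB9 by 0.77 and the peptide transporter TAP1 by 0.73. These 5 lists also passed with an estimated correlation, with adjusted p = 1.68e-05 for interferon, 0.000217 for chemokines, 0.000794 for NF-kB, 0.000794 for cytokines and 0.00182 for antigen presentation.

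Matrix, metabolic and stress genes moved in the same 9 libraries. Of 25 matrix proteases and inhibitors, 14 rose and 5 fell (14 and 5 alone; adjusted p = 0.0457 with an estimated correlation). The collagenase MMP1 went from 237.0 ± 14.2 to 667.5 ± 10.3 CPM, the stromelysin MMP3 from 321.3 ± 14.8 to 1353.3 ± 15.6 CPM, and the elastin-degrading cathepsin CTSS rose by 3.52 ± 0.12. Of 23 glycolysis and hypoxia genes 16 rose and none fell (18 alone; adjusted p = 0.0153 with an estimated correlation), among them HK2 (0.75) and adrenomedullin, ADM (0.93). Of 27 structural matrix genes 15 rose and 2 fell (17 and 2 alone), led by TNC (1.68), ELN (3.65) and COL7A1 (1.32). Of 22 unfolded protein and stress response genes 11 rose (14 rose and 1 fell alone), including HYOU1 (0.40), and of 16 complement genes 5 rose and 1 fell (5 and 1 alone), including C3 (6.22), C1R (1.28) and C1S (0.90). Of 22 TLR4 signalling genes 8 rose (8 alone), with IRAK2 at 1.36 and the inhibitory kinase IRAK3 at 1.91. These last 4 lists passed with the preset correlation only: with an estimated correlation the adjusted p was 0.142 for structural matrix, 0.102 for stress response, 0.0543 for complement and 0.0776 for TLR4 signalling. The receptor TLR4 itself was at 28.6 ± 0.564 CPM with vehicle and 26.2 ± 0.805 CPM with LPS (adjusted p = 0.225). Its partner LY96 was at 7.72 ± 0.16 and 7.3 ± 0.738 CPM (0.785), and the co-receptor CD14 at 0.72 ± 0.0272 and 0.634 ± 0.121 CPM (0.776). The adaptor MYD88 rose by 0.28 ± 0.05.

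The genes that fell the most by the naming rule in these 9 libraries were the urea transporter SLC14A1 (-2.59), MALL (-2.0 ± 0.13), the decoy receptor TNFRSF10D (-1.98 ± 0.05; 153.0 ± 1.62 to 38.1 ± 0.152 CPM), INMT (-1.92) and the estradiol-oxidizing enzyme HSD17B2 (-1.89). They also included the transporter ABCA8 (-1.78), the retinaldehyde dehydrogenase ALDH1A1 (-1.75 ± 0.04; 240.4 ± 0.697 to 70.2 ± 2.88 CPM) and tenascin X, TNXB (-1.74, uncertain because it has a near-identical partial copy). On GRCh38, with positions from GENCODE 29, CXCL8 (ENSG00000169429.12) lies at chromosome 4, 73740506 to 73743716, and CXCL1 (ENSG00000163739.5) at chromosome 4, 73869393 to 73871242. OAS1 lies at chromosome 12, 112906777 to 112933222, C3 at chromosome 19, 6677704 to 6730562, and TNFRSF10D at chromosome 8, 23135588 to 23164030. All are protein-coding genes. Paralogous chemokines such as CXCL1, CXCL2 and CXCL3 share sequence, so their separate levels are less certain than their joint rise. In simulated data, the 12-library fit recovered 14% of 4-fold changes in this comparison (50 genes) and the 9-library fit 98% of 2-fold changes (50 genes). No simulated library carried the other cell type's profile, so the 14% need not hold for the real 12 libraries.

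**Figure D2:**
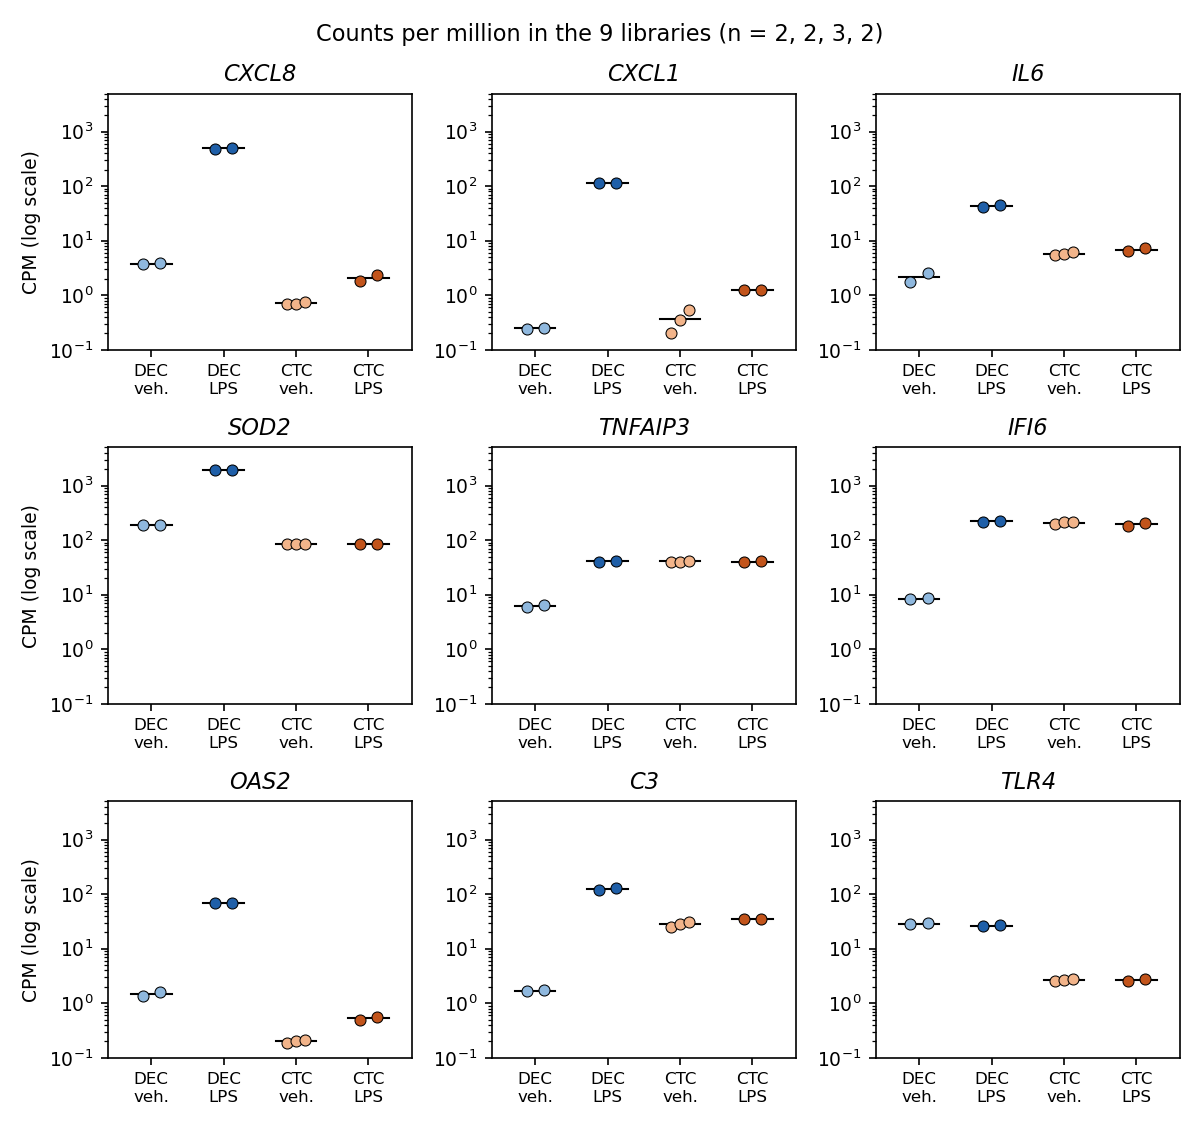
CPM of 9 genes in the 9 libraries (vertical log axis) by group; each point is 1 library (n = 2 DEC vehicle, 2 DEC LPS, 3 CTC vehicle, 2 CTC LPS) and the bar is the group mean. CXCL8 lies at 3.79 CPM in DEC with vehicle and 495.8 CPM with LPS, and at 0.716 and 2.08 CPM in CTC, while TLR4 lies at 28.6 and 26.2 CPM in DEC and at 2.67 and 2.7 CPM in CTC.

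The second comparison asked the same of chorion trophoblast cells. As labelled, no gene passed in edgeR (0 of 20682). There, 1042 genes had an unadjusted p under 0.05, about as many as chance alone gives, and 18 genes passed the threshold in DESeq2. Leaving out the 3 libraries gave a small chemokine response: CXCL1, at 0.365 ± 0.171 CPM with vehicle (n = 3), rose with LPS (n = 2) by a log2 fold change of 1.85 ± 0.24. CXCL8 went from 0.716 ± 0.0464 to 2.08 ± 0.383 CPM (1.55 ± 0.17) and CXCL2 from 0.592 ± 0.1 to 1.28 ± 0.0314 CPM (1.10 ± 0.22). In that fit 84 of 20988 genes passed, 44 higher and 40 lower, and 5 of them by at least 2-fold. With the CTC groups of these libraries fitted alone, 91 genes passed, 45 higher and 46 lower. With the 10 libraries that keep the DEC vehicle library holding 1.55% of trophoblast RNA, 1 gene passed, higher with LPS, and it was among the 84. The CTC libraries are the same in the fits over 10 and 9. The biological coefficient of variation, pooled with DEC, was 0.0431 over the 10 and 0.0295 over the 9. With each of the 9 left out in turn the count was 27 to 117, and the balance turned. Without a CTC vehicle library it was 14 higher and 22 lower, 32 and 57, or 51 and 66. Without a CTC LPS library it was 8 and 19 or 35 and 22, where the LPS arm held 1 library and the spread came from the other groups.

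Besides the chemokines, the naming rule took secreted and signalling genes among those that rose in CTC over the 9 libraries. These were the pentraxin PTX3 (0.439 ± 0.065 to 1.16 ± 0.309 CPM, log2 1.42 ± 0.24), TNFSF15 (0.61), IL11 (0.61; 1.94 ± 0.0402 to 2.96 ± 0.0174 CPM), the inhibin subunit INHBA (0.53) and TNF (0.51; 3.67 ± 0.186 to 5.22 ± 0.483 CPM). Smaller rises were those of SERPINB8 (0.43), TNC (0.40), ODAPH (0.39), HDAC9 (0.38), MTND2P28 (0.36, a mitochondrial pseudogene that can take reads of its source) and FAM83A (0.34). OAS2 of the interferon list rose as well (1.36; 0.202 ± 0.0144 to 0.527 ± 0.0398 CPM). The genes that fell included the cyclin-dependent kinase inhibitor CDKN1C (194.7 ± 3.88 to 154.6 ± 7.91 CPM, -0.33 ± 0.04, adjusted p = 8.23e-06; chromosome 11, 2883213 to 2885773), the paternally expressed gene PEG3 (220.9 ± 4.52 to 179.4 ± 0.483 CPM, -0.30 ± 0.04) and GCM1 (-0.32 ± 0.06), the transcription factor that drives trophoblast fusion. GADD45G (-0.45), NPNT (-0.31), MUC15 (-0.30), KRT23 (-0.29) and the riboflavin transporter SLC52A1 (-0.29, with a close paralog) fell by similar amounts. TLR4 was at 2.67 ± 0.121 CPM with vehicle and 2.7 ± 0.139 CPM with LPS, and CD14 at 0.507 ± 0.101 and 0.503 ± 0.0282 CPM. MYD88 was at 35.1 ± 1.24 and 36.0 ± 0.474 CPM, and LY96 at 0.0415 ± 0.0262 and 0.0362 ± 0.0512 CPM. None of the 4 passed. LY96 rested on 6 and 3 counts over the groups, a ratio of 1.06 of vehicle to LPS with a 95% counting interval of 0.226 to 6.55.

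By list, in the 9 libraries, 12 of the 25 passed for CTC with the preset correlation, 11 ranking higher and 1 lower, and 2 with an estimated correlation. The cytokines had 2 of 21 members higher (5 when adjusted over the list alone) and the chemokines 3 of 16 (4 alone), each with an adjusted p of 0.0446 with an estimated correlation. The other calls were lost with it. The NF-kB list had 1 of 23 higher (7 higher and 1 lower alone; adjusted p = 0.12), represented by ICAM1 (0.30). Matrix proteases had 3 of 25 higher (7 alone; 0.126), which were the plasminogen activator PLAU (0.28), its receptor PLAUR (0.26) and its inhibitor SERPINE1 (0.24). The interferon list had 1 of 43 higher (1 alone; adjusted p = 0.126), smooth muscle markers 1 of 12 (5 alone; 0.0571), namely TAGLN (0.32), and structural matrix 2 of 27 (5 alone; 0.658). Tolerance and checkpoint genes had 1 of 22 higher (2 alone; adjusted p = 0.12), antigen presentation 0 of 19 (1 alone; 0.19), prostaglandin synthesis 0 of 23 (0 alone; 0.126) and decidualization 0 of 15 (3 alone; 0.12). Trophoblast markers ranked lower, with PEG10 (3246.5 ± 29.7 to 2674.5 ± 67.3 CPM) and MSX2 (-0.18) lower and KRT7 (0.19) higher of 23 (2 higher and 3 lower alone; adjusted p = 0.523). Over the 12 libraries as labelled, 15 lists passed, 14 higher and 1 lower, with no member called over all genes, 17 of 22 stromal markers higher when adjusted over that list alone, and adjusted p values of at least 0.483 with an estimated correlation. There, smooth muscle markers had a median log2 difference of 3.15 and trophoblast markers of -0.57, in a contrast in which 1 of 3 CTC LPS libraries held decidual-specific genes at 98.8% of their decidual level.

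**Figure D3:**
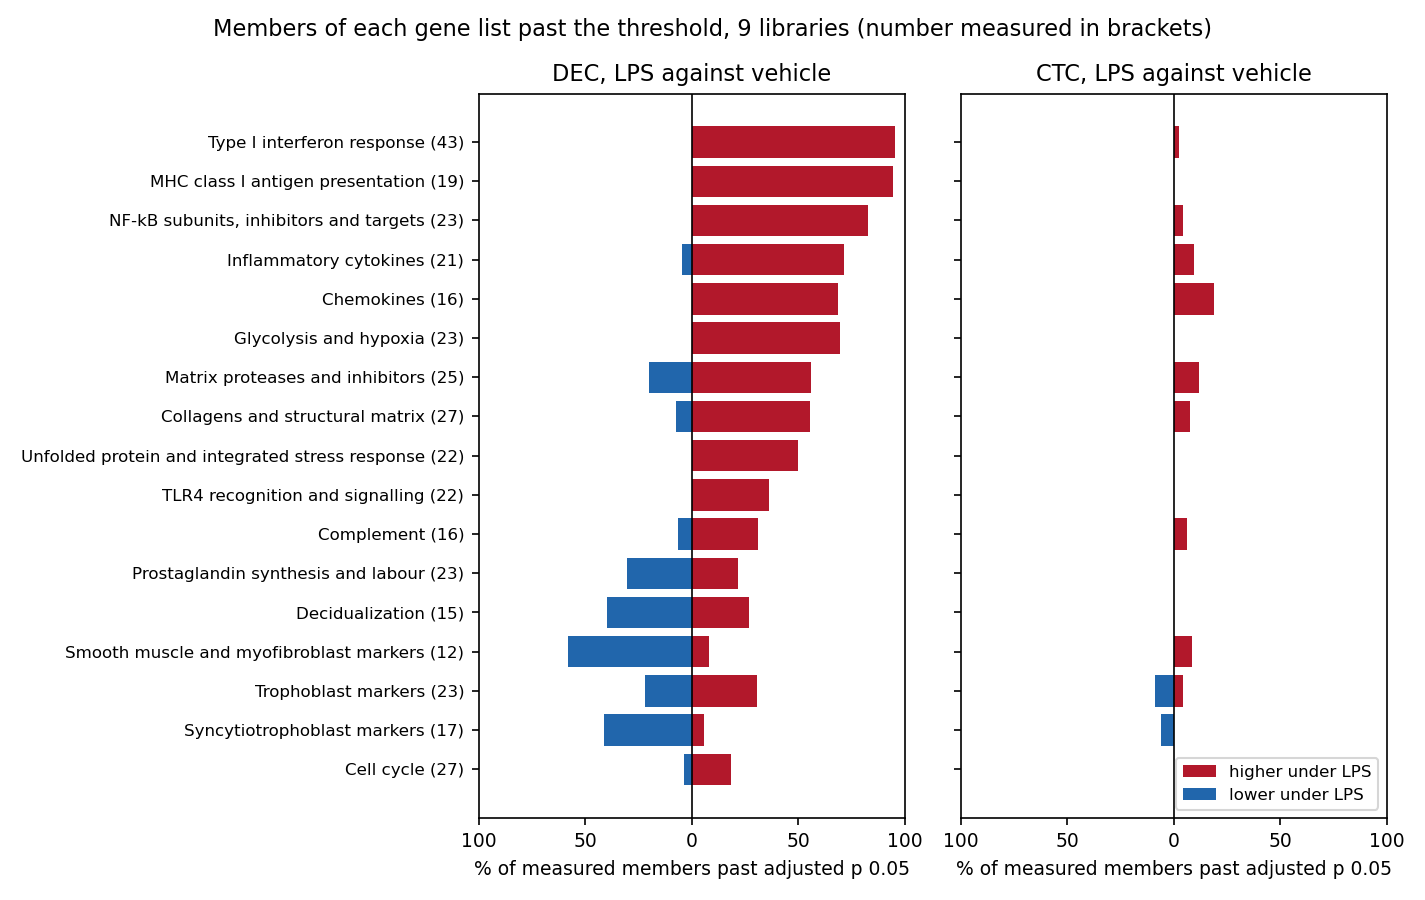
Percent of the measured members of 17 gene lists past an adjusted p of 0.05 with LPS in the 9 libraries (horizontal axis), higher to the right and lower to the left, in DEC (left panel) and CTC (right panel); the number measured follows each name. In DEC 41 of 43 interferon genes rose, and in CTC 1 of 43.

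The third comparison was the difference of the LPS effects between the cell types, CTC minus DEC, which the title's theme of unequal responses raises. The LPS effect on IFI6 was lower in CTC than in DEC by a log2 difference of -4.30 ± 0.32 over the 12 libraries as labelled (adjusted p = 0.00226). IFI6 already stood at 208.6 ± 6.95 CPM in CTC with vehicle, near its level in DEC with LPS (212.8 ± 12.9 CPM). As in the first comparison, the fit as labelled favours genes with such matching levels. Over those libraries 8 genes passed, 1 with the higher effect in CTC and 7 with the lower. DESeq2 gave 150 (70 higher and 80 lower), no filter 5, a replicate block 0 and each library left out in turn 2 to 8. Of 100 splits of the libraries into such groups, 12 gave at least 8 genes, the real split included. Some possible splits keep the true DEC grouping, so this share is not a chance rate. The naming rule took CMPK2 (-3.48 ± 0.33), LRRC15 (-3.0), C15orf48 (-2.86), TNFAIP3 (-2.42 ± 0.22) and CEMIP2 (-0.83) besides IFI6, and MEST (0.92 ± 0.1) on the other side. All 8 were called with the same sign in the 9 libraries, where 1799 genes passed, 886 with the higher and 913 with the lower effect in CTC (728 and 638 without 1 DEC vehicle library). With the 10 libraries 1050 genes passed, 454 higher and 596 lower, and 1035 of them were shared. A higher effect in CTC can be a fall in DEC: in the 9 libraries only 44 genes passed as higher with LPS in CTC. The antiviral OAS1 (-7.77), the chemokines CXCL6 (-7.32), CXCL1 (-7.00 ± 0.4), CXCL8 (-5.50 ± 0.23) and CXCL3 (-5.96), and C3 (-5.88 ± 0.12), MX2 (-5.82), IL6 (-4.09) and SOD2 (-3.35 ± 0.06) had the lower effect in CTC. CXCL8 with LPS stood at 495.8 ± 21.3 CPM in DEC and at 2.08 ± 0.383 CPM in CTC (n = 2 each).

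In the 9 libraries the lower effect in CTC held for 34 of 43 interferon genes (37 alone), 16 of 23 NF-kB genes (17 alone), 14 of 19 antigen presentation genes (17 alone), 14 of 23 glycolysis and hypoxia genes (16 alone), 8 of 16 chemokines (9 alone) and 7 of 21 cytokines, with 1 cytokine higher (10 lower and 1 higher alone). These 6 lists passed with an estimated correlation too, the largest adjusted p being 0.0132. The calls of 5 more lists were lost with it: TLR4 signalling (7 of 22 lower; adjusted p = 0.0598), stress response (9 of 22 lower; 0.114), smooth muscle (5 of 12 higher and 2 lower; 0.108), complement (3 of 16 lower and 1 higher; 0.192) and structural matrix (10 of 27 lower and 1 higher; 0.293). AKR1B1 (-2.05 ± 0.06), TNC (-1.28), HK2 (-0.72), PSME2 (-0.88) and the smooth muscle regulator MYOCD (-3.38 ± 0.14) were among the lower. The genes with the higher effect in CTC included MALL (3.67), MRAP2 (2.73), SLC14A1 (2.43), TNFRSF10D (2.03 ± 0.1), TNXB (1.90 ± 0.17), the integrin ITGA6 (1.11 ± 0.06), PTGES (0.97) and GJA1 (0.65). In DEC, MALL (-2.0), SLC14A1 (-2.59), TNFRSF10D (-1.98), TNXB (-1.74), ITGA6 (-1.06), PTGES (-0.91) and GJA1 (-0.64) fell with LPS. Their differences include that fall and do not by themselves show a rise in CTC. The counting error of the difference was 0.81 for MALL and 0.72 for MRAP2. Also called were RELN, TRPV6, OTOGL, RFLNA and CSF3, each with at most 3 counts in a group, so that the fitted difference depends on the prior count. RELN was at 14 and 8.29 CPM in DEC and 0.00752 and 0.108 CPM in CTC (vehicle and LPS), and TRPV6 at 0.128 and 0.0116 CPM and 12 and 12.3 CPM. In the same order OTOGL was at 0.198 and 0.0342 CPM and 0.956 and 1.03 CPM, RFLNA at 0 and 0.204 CPM and 4.13 and 3.88 CPM, and CSF3 at 0.174 and 19.7 CPM and 0.012 and 0.0239 CPM. Over the 12 libraries as labelled, 9 lists passed, none with an estimated correlation (adjusted p of at least 0.722). Antigen presentation, matrix proteases, structural matrix, inflammasome, decidualization, stromal and smooth muscle markers ranked higher in CTC, and cell cycle and trophoblast markers lower. That contrast takes in both libraries with the other cell type's profile, and its smooth muscle markers had a median of 3.89.

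Across the genes called in either cell type, the LPS fold changes of DEC and CTC correlated with Pearson's r of 0.521 and Spearman's rho of 0.404 over the 43 genes as labelled, and with 0.143 and 0.163 over the 3754 genes of the 9 libraries. Pearson's r as labelled was -0.02 with DESeq2 and 0.067 to 0.655 with each library left out in turn, so its sign and size were not settled. Genes are not independent replicates, so no p is given. In the 9 libraries 40 genes were called in both cell types, 30 with the same sign and the rest with opposite signs. Of the 40, 24 rose in both and 6 fell in both, where independent lists would share 3.72 and 3.69. The comparisons share no library. CXCL1, CXCL2, CXCL8, ICAM1, C3, TNC and OAS2 were among those that rose in both.

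The fourth comparison set the vehicle cultures against each other, CTC against DEC, to give the state in which each met LPS. CTC were epithelial: keratin KRT8 stood at 4599.3 ± 182.9 CPM (n = 3) against 15.6 ± 0.301 CPM in the 2 DEC vehicle libraries, and E-cadherin, CDH1, at 1326.3 ± 30.6 against 0.417 ± 0.00821 CPM. DEC were mesenchymal, with vimentin, VIM, at 2063.3 ± 14.2 CPM against 1.26 ± 0.143 CPM and the collagen COL6A3 at 3850.4 ± 140.4 against 7.55 ± 0.634 CPM. As labelled, 11743 of 20682 genes differed, 5613 higher and 6130 lower in CTC. This count fell to between 12 and 18 when any single vehicle library was left out. In the 9 libraries 17203 of 20988 differed, 9105 higher and 8098 lower, and 11682 of the former calls were shared, all with the same sign. With the 10 libraries 17343 differed. The receptor transcript TLR4 was lower in CTC by 3.78 on the log2 scale (a log2 difference of -3.78; chromosome 9, 117704175 to 117724730). LY96, which binds LPS with it, was lower by a log2 difference of -7.90 (7.72 ± 0.16 against 0.0415 ± 0.0262 CPM; chromosome 8, 73991352 to 74029087). CD14 (-0.89 ± 0.25) and MYD88 (-0.74 ± 0.04) were closer.

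The genes furthest apart as labelled were ERVE-1, CRACDL, CYP8B1, ARHGAP40, CTAG2, SPAG6, GABRG2 and THNSL2 on the CTC side, with 0 counts in all 3 DEC vehicle libraries and 2.04 to 4.14 CPM in CTC. ERVE-1 and CTAG2 are uncertain because they have close copies. On the DEC side they were NALF1 (40.2 ± 0.961 against 0.00691 ± 0.012 CPM), ADAMTS2, SSTR1, EBF1, PRRX1, CNTN3, CDH11 and FAM20C. In the 9 libraries, against a floor of 3 counts over the group, the thiamine transporter SLC19A3 was at least 1789.4-fold higher in CTC, SIGLEC5 (with a near-identical copy, hence uncertain) at least 1765.9-fold, FABP7 at least 1377.5-fold and IGSF9 at least 1300.2-fold. FGFBP1 was at least 801.2-fold higher, SLC52A3 at least 711-fold, CEBPA at least 648.4-fold and ERVV-2 (also uncertain) at least 610.3-fold. The secretory kinase FAM20C was at least 5546.5-fold lower, CNTN3 at least 1039.2-fold, GFRA1 at least 849.2-fold and EBF1 at least 710.6-fold. CDH11 had 3 counts in CTC, a ratio of 8694.1 (95% counting interval 2974.4 to 42163.4). The mesenchymal factor PRRX1 stood at 198.5 ± 1.71 against 0.0298 ± 0.0142 CPM, ADAMTS2 at 132.9 ± 4.58 against 0.0295 ± 0.0347 CPM and SSTR1 at 423.1 ± 5.91 against 0.0927 ± 0.0274 CPM. These intervals and floors cover counting error only. The floors of the genes higher in CTC rest on the DEC vehicle libraries that were kept. The DEC vehicle library left out held trophoblast-specific genes at a median of 1.55% of their trophoblast level. The 0 counts in DEC, and with them the size of these floors, therefore depend in part on leaving it out.

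By list, in the 9 libraries, 22 of 23 trophoblast markers were higher and 1 lower in CTC, and 20 of 27 cell cycle genes higher and 6 lower. All 22 stromal and all 12 smooth muscle markers were lower, among them ACTA2 (7.0 ± 0.582 against 622.6 ± 5.99 CPM). Antigen presentation (19 of 19 lower), structural matrix (23 lower and 4 higher of 27), matrix proteases (19 and 6 of 25) and interferon response (29 and 10 of 43) ranked lower in CTC. So did inflammasome (15 and 3 of 20), decidualization (12 and 3 of 15), NRF2 (17 and 8 of 26), NF-kB (16 and 7 of 23) and complement (10 and 3 of 16). Examples were MMP3 (321.3 CPM in DEC against 0.158 CPM), and the interferon-induced IFIT3 (116.6 against 0.766 CPM) and GBP1 (91.1 against 0.902 CPM). Others were the metallothionein MT2A (862.4 against 12.8 CPM) and the homeobox gene HOXA11 (39.5 against 0.0533 CPM). These 13 lists passed with the preset correlation only. With an estimated correlation the smallest adjusted p in camera was 0.145. Over the 10 libraries 12 lists passed with the preset correlation and 6 with an estimated one. As labelled 9 lists passed, 2 higher and 7 lower, and none with an estimated correlation (adjusted p of at least 0.656). One DEC vehicle library of that fit held trophoblast RNA at 1.55%.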

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

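Of the tests in this part, the difference of effects over the 12 libraries, the simulated recovery and the counts over other splits were chosen before their results were seen, and the others after. A difference of the LPS effects between the cell types, tested directly as CTC minus DEC, picked out these results. It was past the threshold for 8 genes and 9 gene lists over the 12 libraries as labelled, and for 1799 genes and 11 lists over the 9 libraries. With an estimated correlation 0 of the 9 lists and 6 of the 11 were left. In the 9, the lower effect in CTC covered 16 NF-kB genes, 7 cytokines, 8 chemokines, 34 interferon genes, 14 antigen presentation genes and 14 glycolysis and hypoxia genes. The log2 differences of the named genes were 3.67 for MALL, 2.73 for MRAP2, 2.43 for SLC14A1, 2.03 for TNFRSF10D, 1.90 for TNXB, -7.77 for OAS1, -7.32 for CXCL6, -7.00 for CXCL1, -5.96 for CXCL3, -5.88 for C3 and -5.82 for MX2. For RELN, TRPV6, OTOGL, RFLNA and CSF3, which had at most 3 counts in a group, the adjusted p in edgeR was 0.00257, 0.0391, 0.0224, 0.00022 and 0.036.

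One library in each LPS group carried the profile of the other cell type. A set of 78 genes was taken that rose at least 2-fold in DEC, passed a minimum level there with LPS and stood well above the CTC LPS level. Over these genes the library labelled CTC LPS stood at a median ratio of 1.01 to the remaining DEC LPS libraries (quartiles 0.973 and 1.05). The ratio was 0.357 for DEC vehicle libraries. The library labelled DEC LPS lay nearer the LPS level for 42 of 44 genes raised and 37 of 40 lowered in CTC. Both results are what an exchange of these 2 labels would give. A mixture of the cell types is argued against by the genes of the labelled type, which stood at no more than 0.11% of their usual level. A change of cell identity under LPS could not be tested. In the remaining LPS libraries the other type's genes, chosen in vehicle libraries alone (213 trophoblast and 155 decidual), reached 0.153% at most. Those libraries were the ones left after the libraries with the other profile were taken out, so a low share in them was set in advance. The labels were kept as given, and no record outside the values was used.

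One DEC vehicle library held trophoblast-specific RNA at a median of 1.55% of its trophoblast level. All of the trophoblast-specific genes, 100%, lay within 2-fold of that share, which is consistent with RNA or cells of the trophoblast cultures carried over. A part of the trophoblast programme switched on in decidual cells would spread the genes over unequal shares and is argued against by the same 100%. The step at which such carry-over may have happened, in culture, in library making or in sequencing, was not tested and stays open.

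LPS changed 3710 genes in DEC and 84 in CTC over the 9 libraries. Simulated 2-fold changes were recovered in CTC at 102% of the rate in DEC. Recovery of such changes was close to complete in both cell types (98% in DEC and 100% in CTC). Most calls in both cell types were below 2-fold. At the smallest simulated fold recovery was 74% in DEC and 70% in CTC, and at the next larger one 100% and 90%. Calls of at least 2-fold numbered 414 in DEC and 5 in CTC. These values argue against lower power in CTC as the whole source of the gap, for changes of the simulated sizes. A somewhat lower power in CTC for changes below 2-fold is not excluded. Decidual LPS RNA carried into the CTC libraries was looked at as the source of the CTC calls that rose. They would need a median share of 6.26% (0.275% to 16.7% for the chemokines). The median rise of decidual-specific genes chosen in vehicle libraries was 0% of that (quartiles -0.0447 and 0.0276, highest 0.491 percentage points). A steady share coming from DEC LPS cultures would give no such rise, so this test does not cover it. In the CTC LPS libraries kept, decidual-specific genes stood at 0.115% and 0.125% in all. These shares are below those needed, which argues against carry-over as the whole source. A part of the chemokine rises is not excluded, most of all for CXCL8, which needed the smallest share (0.275%). A candidate explanation is that CTC held less of the receptor transcripts TLR4 and LY96, by log2 differences of at least 3.78 in size (-3.78 for TLR4). It cannot be told apart from cell type, origin and medium because all of them differ together. A lasting difference in how the cells respond to endotoxin also stays open, untested.

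Other splits of the libraries into groups of the same sizes were drawn for each count over the 12 libraries as labelled. For the difference of the LPS effects, 12 of 100 splits, the real one counted here and below, gave at least the real 8 genes (highest other 15). At least the real 9 lists came from 71 of 100 (highest other 17). Each cell type was regrouped on its own, so some possible splits keep the true DEC grouping and with it the DEC LPS effect. These shares are therefore not chance rates, and chance could be neither excluded nor shown for either count. The other comparisons allow 10 splits, too few for a share under 0.05. For LPS in DEC the real split gave 43 genes and the highest other 0 (1 of 10 splits as large), with 9 lists against 16 (4 of 10). For LPS in CTC the real split and the highest other gave 0 genes (10 of 10), with 15 lists against 18 (6 of 10). For the vehicle cultures the real split gave 11743 genes and the highest other 0 (1 of 10).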

How the results depend on the processing

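The fits over 10 and 9 libraries, and all alternatives run on the 9, were chosen after seeing the data; where a value moved and no cause is given, the cause was not tested. Counts are for LPS in DEC, LPS in CTC, the difference of effects and the vehicle cultures. As labelled (43, 0, 8 and 11743 genes; 9, 15 and 9 lists; correlation 0.521), size factors in edgeR kept every count within 1.5 times. The DESeq2 Wald test gave 281, 18 and 150 genes and a correlation of -0.02, which reversed it. Without a low-count filter 23, 5 (difference) and 24 (vehicle) genes passed, and with the 2 groups fitted alone 2 in DEC. An estimated correlation left 0, 0 and 0 lists. Leaving out 2 libraries gave 2797, 1 and 1050 genes and a correlation of 0.151; leaving out 3 gave 3710, 84 and 1799 and 0.143. Each library left out in turn gave 15 to 67, 0 to 0, 2 to 8 and 12 to 14958 genes, 7 to 11, 1 to 16 and 8 to 10 lists, and correlations of 0.067 to 0.655; the 1 list followed from leaving out a CTC LPS library, and leaving out any vehicle library gave 12 to 18 vehicle genes. In the 9 libraries, the Wald test moved the correlation to 0.202, no filter gave 132 CTC genes, and an estimated correlation left 7, 2 and 6 lists. Keeping the admixed vehicle library gave 1 CTC gene and 1050 for the difference, and taking all 12 as labelled gave 43, 0, 8 and 0.521. With the admixed library kept the CTC libraries are the same, so that CTC count moved through the fit shared with DEC. The CTC groups fitted alone gave 91. Each of the 9 left out in turn gave 2666 to 3921, 27 to 117, 1345 to 1799 and 16462 to 17647 genes, 12 to 14, 9 to 13 and 11 to 12 lists, and correlations of 0.09 to 0.155 (0.09 and 0.118 without a CTC LPS library). Where 1 library was left in a group, as for DEC or CTC LPS here, it was assumed to vary like the others.

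The replicate block, run although no label gives the numbers a meaning, left 1 gene in DEC, 0 in CTC, 0 in the difference and 8 in vehicle, and 5 lists for the difference. Same-numbered libraries had correlations of -0.5 to 0.32 over 6 pairs, 1 above 0.1, and of -0.08 to 0 over 4 pairs in the 10 libraries. These values gave no clear sign of pairing by number, but so few pairs cannot exclude it. With the block the 10 libraries gave 2409, 0 and 956 genes and a correlation of 0.108, and the CTC log2 fold changes of TLR4 and CD14 were -0.02 and -0.16, reversed from values that had not passed.

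Of the 43 gene results named as labelled, none reversed; 1 lost its call with size factors, 13 with the Wald test, 24 without the filter and 42 with the block. With the groups alone, where the difference was not run, 18 lost it and 18 kept it. With each library left out in turn the call was lost 245 times and kept 271 times. Of the 177 gene results of the 9 libraries run in the alternatives, 16, 0 and 1 lost it with the Wald test, size factors and no filter. Where fewer were run, 1 lost it and 142 kept it with the groups alone, and 38 lost it and 100 kept it with the 10 libraries and the block. Of the 177, 33 lost it with the admixed library kept and 120 over the 12 as labelled, where 17 reversed, with the other type's profile in 1 library of each LPS group: PTGES in DEC (1.81); TNF (-0.08), ODAPH (-0.14), FAM83A (-0.26), KRT7 (-0.39) and LY96 (6.57) in CTC; and, in the difference, TRPV6 (-4.88), OTOGL (-1.28), CSF3 (2.86), MX2 (3.07), SOD2 (0.63), CXCL8 (1.94), PSME2 (0.85), PTGES (-2.30), TNC (4.81), LY96 (7.29) and MYD88 (0.45). With each of the 9 left out the call was lost 70 times and unchanged 1511 times. Receptor genes that never passed also changed sign: LY96 in the difference with the admixed library kept (0.06), and with 1 library left out the ranges were -0.16 to 0.04 for LY96 and -0.37 to 0.02 for CD14 in DEC, -3.80 to 0.87 for LY96, -0.04 to 0.07 for TLR4 and -0.17 to 0.15 for CD14 in CTC, and -3.74 to 0.92 for LY96 in the difference. Depth limits genes near 3 counts per group, such as LY96 in CTC.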

Other observations

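Hormone and prostaglandin genes of decidual cells moved in both directions in the 9 libraries. Of 23 prostaglandin and labour genes 5 rose and 7 fell with LPS (6 and 7 when adjusted over the list alone). AKR1B1 went from 287.4 ± 6.4 to 1186.2 ± 33.6 CPM and PTGS2 from 0.314 ± 0.0339 to 2.23 ± 0.23 CPM (n = 2 each), while the prostaglandin E synthase PTGES fell from 13.1 ± 0.494 to 6.84 ± 0.843 CPM and the gap junction gene GJA1 from 499.0 ± 8.02 to 315.8 ± 6.5 CPM. The oxytocin receptor OXTR stood at 819.2 ± 31.4 CPM in DEC and 5.5 ± 0.714 CPM in CTC with vehicle, and PTGES at 13.1 and 156.3 ± 5.09 CPM. Of 15 decidualization genes 4 rose and 6 fell (4 and 6 alone); the cortisol-activating enzyme HSD11B1 went from 9.13 ± 1.2 to 30.6 ± 0.164 CPM, the deiodinase DIO2 rose by 1.08 ± 0.05 and CEBPB by 0.55 on the log2 scale. Neither list passed camera (adjusted p = 0.99 and 0.454).

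Of 12 smooth muscle markers 1 rose and 7 fell in DEC (2 and 7 alone; camera adjusted p = 0.159): the coactivator MYOCD, which drives smooth muscle genes, went from 4.17 ± 0.289 to 38.1 ± 0.331 CPM, while ACTA2 went from 622.6 ± 5.99 to 473.8 ± 15.0 CPM and CALD1 from 6854.9 ± 212.0 to 5404.7 ± 30.6 CPM. Of 17 syncytiotrophoblast genes, some of which decidual cells also express, 1 rose and 7 fell (2 and 7 alone; adjusted p = 0.297); PAPPA, a protease that frees insulin-like growth factor, rose by 0.75, and PSG5 and SDC1 fell to -0.27 and -0.37. Of 26 NRF2 and metal stress genes 7 rose and 4 fell (8 and 4 alone; adjusted p = 0.0895), among them MT2A at 0.67 and the ferritin FTH1 at 0.66. Of 23 trophoblast markers 7 rose and 5 fell (8 and 5 alone; adjusted p = 0.297), where ITGA6 fell by a log2 change of -1.06 ± 0.04 and KRT19 of -0.91, and of 22 stromal markers 7 rose and 7 fell (9 and 7 alone; adjusted p = 0.99), where PDGFRA fell by a log2 change of -0.59. Inflammasome genes had 6 higher and 5 lower of 20 (7 and 5 alone; adjusted p = 0.587), tolerance genes 7 and 7 of 22 (7 and 7 alone; 0.297) and cell cycle genes 5 and 1 of 27 (6 and 1 alone; 0.297). Markers of macrophages (0 higher and 1 lower of 6; adjusted p = 0.843), NK and T cells (0 and 1 of 7; 0.461), endothelium (0 and 1 of 9; 0.516) and endometrial glands (1 and 1 of 7; 0.925) had few measured members.

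In CTC, the aromatase CYP19A1, which makes estrogen and is a marker of trophoblast fusion, went from 125.8 ± 3.58 to 108.6 ± 2.09 CPM with LPS (log2 fold change -0.21 ± 0.04, adjusted p = 0.0026 in edgeR), and it was the 1 called gene of 17 in its list, lower (1 higher and 3 lower alone; camera adjusted p = 0.469). Of the genes raised in DEC, 56.5% had a positive fold change in CTC, against 49.7% of all tested genes, as a description across genes.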
